A study of Mus musculus with 12 samples.

How the data were processed

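RNA was extracted with TRIzol, and sequencing libraries were made from 1 µg of total RNA with a stranded mRNA kit from Illumina, per the labels' protocols. The 12 libraries came from 2 mouse tumour lines grown in DMEM, MB49 (bladder cancer) and KPC (pancreatic ductal adenocarcinoma). Each line had 3 control and 3 irradiated (8 Gy) libraries. Treated cells were cultured for 48 h, and no culture time is given for the controls. The submitters' processing notes name fastp, HISAT2 and StringTie and the genome build GRCm39, with no versions or order, and the tool that counted reads per gene is not given in the sources used here. The deposited table holds estimated counts per gene, not scaled between libraries: 6.2 to 8.7% of a library's values were not whole numbers, and library totals differed. The strand setting of the counting is not given either, so reads of a gene and of an overlapping antisense gene, or of near-identical copies within a family such as the H2-Q, Gbp and interferon-inducible GTPase genes, may be shared between them. The authors' 4 group-mean columns and the column of gene length stand in the same table; the means were not used, and the length served one check. No coordinates are given, because the annotation at hand was of another build than the deposited table and was used only for gene properties by gene identifier. Groups and replicate numbers were taken from the sample labels.

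The table had 57180 rows. Of these, 525 had no gene symbol, which took 0.18 to 0.45% of a library's counts, and 53 of them passed the filter; they keep their gene identifier and stayed in the library sizes. Where a symbol repeated, 233 rows were given distinct names. The estimated counts were rounded to whole numbers first. Genes with low counts were removed with edgeR's filterByExpr by group, which left 14362 and removed 42818. Libraries were scaled by TMM factors of 0.829 to 1.18, and CPM values use these factors, except that the levels of immune cell markers and the rise of B2m beside them use library totals. A quasi-likelihood model with 1 coefficient per group was fitted to all 12 libraries, robustly, with 8 residual degrees of freedom and a common biological coefficient of variation of 0.150. Tests were 2-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors of log2 fold changes are approximate, computed as the size of the fold change over the square root of the F statistic. The 4 comparisons were 8 Gy against control in each line, the difference of the 2 responses, and KPC controls against MB49 controls. All were fixed before the data were examined, with the gene lists and the rule for naming genes. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (version 1.17.8).

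The 26 gene lists covered p53 targets, G2/M and mitosis, DNA replication, DNA repair, replication histones, SASP factors, interferon-stimulated genes, MHC class I presentation, T cell ligands, cGAS and STING signalling, NF-kB targets, vesicle biogenesis, lysosome, cholesterol synthesis, the integrated stress and unfolded protein responses, matrix and mesenchymal genes, epithelial, urothelial and pancreatic duct markers, immune cell markers, fibroblast and endothelial markers, BCL2 family and apoptosis genes, mitochondrially encoded genes, cytosolic ribosomal proteins, heat shock and immediate early genes. Some genes stand on 2 lists. Each list with at least 5 tested genes was tested with limma's camera on voom-weighted log2 CPM, with a preset correlation of 0.01 and again with a correlation estimated per list, adjusted over the 26 lists. With the estimated correlation, 3 of the 7 calls in MB49, 4 of the 10 in KPC and 2 of the 9 for the difference were made. limma's fry, which tests a list without regard to the other genes, was planned and run beside camera. Except for NF-kB targets in the difference, its results are not given here.

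Genes were named by this rule: 15 anchor genes in every case (Trp53, Cdkn1a, Cdkn2a, Cdkn2b, Mdm2, Lmnb1, Mki67, Glb1, Il6, Cxcl10, Ccl2, B2m, H2-K1, Cd274 and Calr); from each list, up to 3 genes that rose and 3 that fell most among those called, with at least 1 CPM in either group, or the most expressed member of a list with none; and over all genes, the 8 largest rises and 8 largest falls among those called with at least 5 CPM in the higher group, no overlap between the 3 libraries of each group, and a symbol that is not a clone or model name. The difference of responses took the same from its own ranking, with the anchors and list genes that passed, and the control comparison took the 6 highest genes of each line and the epithelial, urothelial, pancreatic and mesenchymal markers. The text takes a part of these. Named genes that passed the test in a comparison of 2 groups were checked for overlap between libraries. In each gene checked, the 3 libraries of one group lay all above or all below the 3 of the other. The rule demanded this of the largest rises and falls, and the genes were chosen for passing the test. The separation is therefore no further evidence of a change. Genes outside the rule are said to be chosen or named after their values were seen.

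A fold against a group with 0 counts is given as a lower bound, with 3 counts over that group as the floor; with 1 to 3 counts the ratio is given with its exact 95% interval. In a single library, 3 counts were 0.109 to 0.173 CPM. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The fit was tested on simulated counts of 13517 genes, drawn with the real library sizes and the average of the 2 control means as every group's base. It recovered 27.7% of genes changed 1.5-fold, 64.5% of those changed 2-fold and 92.3% of those changed 4-fold for MB49, with 6.3% false calls. For KPC these were 38.5%, 78.5% and 93.8%, with 6.2% false calls, and for the controls 34.8%, 79.7% and 93.2%, with 6.5%. For the difference of responses 48.2% of all changed genes were recovered, with 6.1% false calls. These simulations changed 189 to 194 genes per comparison of 2 groups, against 9086 to 9672 genes called in the real data. The shares may therefore not hold where most genes change. In a simulation with the vesicle list raised in MB49, camera called that list and 0 of the others of 24 lists tested. The simulated genes varied independently, so this could not show how camera treats lists whose genes vary together. Libraries of a group were compared pairwise, and their chi-square per gene of 7.46 to 143.86 showed no library deposited again as another.

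Alternatives fixed before the data were examined were DESeq2's size factors and upper quartile factors in the same fit, DESeq2's own test, limma-voom, no filter and a stricter filter on low counts (1 CPM in at least 3 libraries), a fit of only the 6 libraries compared, the replicate number as a block, a test against a log2 fold change of 1, each library left out in turn and, for the lists, ranks and the estimated correlation. Added after the data were seen were leaving out the 18S row, scaling by library totals only, and an offset that removes a trend with gene length. A scan of the pathways annotated in the deposited table and of classes of transcripts was also chosen after the data were seen.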

Results

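RNA was sequenced from cultures of 2 mouse tumour cell lines, each with an untreated control group and a group given 8 Gy of radiation. MB49 is a bladder cancer line, and KPC is a pancreatic ductal adenocarcinoma line. Each of the 4 groups had 3 libraries, and the treated cells were collected after 48 h of culture. The controls' culture time is not given, so a difference in it cannot be told apart from the dose. The series concerns nanovesicles from senescent tumour cells given to strengthen radiotherapy. The comparisons ask how each line's transcriptome stood after radiation and whether the lines differed in this. Its design text speaks of senescent as well as ordinary cells, while the label of each library gives only control or 8 Gy. Whether any cells had been made senescent beforehand is not stated per library. The 12 libraries held 19006015 to 26337950 counts, and 12216 to 13045 genes had at least 10 counts. Levels below are CPM, counts scaled to library size, as mean ± SD (n = 3), and fold changes are log2 values ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14362 genes. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries. The first principal component took 63.7% of the variance and the second 23.8%. Libraries of a group correlated across genes with r of 0.975 to 0.990, against 0.901 between the MB49 control and 8 Gy group means and 0.909 between those of KPC. In KPC control replicate 1 the 18S ribosomal RNA gene Rn18s-rs5 took 5.11% of all counts, against 0.14 to 0.55% in the other 11 libraries.

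The untreated lines were compared as the baseline for both responses, gene by gene and without a test of gene lists. Krt19, a keratin of ductal epithelium, was at 80.7 ± 12.9 CPM in KPC controls and 3.85 ± 2.48 CPM in MB49 controls, a difference of 4.41 ± 0.32 (adjusted p = 5.08e-08), or 5.03 without MB49 control replicate 3. The pancreatic transcription factor gene Pdx1 was higher in KPC by 2.15 ± 0.13 (adjusted p = 8.48e-11). Foxa2, a transcription factor gene of endoderm-derived epithelia, had 893 counts in the KPC controls and 0 in the MB49 controls, at least 308-fold higher in KPC against a floor of 3 counts over the group. MB49 controls had more Vim (3198 ± 470 against 669.5 ± 18.0 CPM), the mesenchymal intermediate filament gene, with a KPC minus MB49 difference of -2.26 ± 0.13 (adjusted p = 1.07e-10). Snai2, a repressor of epithelial genes, had 7052 counts in the MB49 controls and 0 in the KPC controls, at least 2270-fold higher in MB49. Markers of a kind did not all go one way: the simple epithelial keratin genes Krt8 and Krt18 were lower in KPC (-1.73 ± 0.14 and -1.89 ± 0.14, adjusted p = 6.42e-09 and 1.41e-09). The fibronectin gene Fn1 was higher in KPC (2.85 ± 0.24, adjusted p = 2.05e-08). Sox9, a ductal marker, and Gata3, a urothelial marker, did not pass the test (0.15 ± 0.14 and 0.20 ± 0.14, adjusted p = 0.368 and 0.226). Across all genes, 4735 were higher and 4937 lower in KPC controls, 67.3% of those tested. Of 129 genes at 10 CPM or more in MB49 controls and under 0.5 CPM in KPC controls, 108 were at 10 CPM or more in irradiated MB49 cells and 103 were under 0.5 CPM in irradiated KPC cells. Of 174 genes with the opposite pattern, 129 were at 10 CPM or more in irradiated KPC cells and 141 were under 0.5 CPM in irradiated MB49 cells.

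After 8 Gy, MB49 cells carried a broad rise of interferon-stimulated and antigen presentation genes. With an estimated correlation the first list was called (adjusted p = 0.00973) and the second was not (0.0847). Cxcl10, a chemokine gene that draws T cells, rose from 23.1 ± 1.44 to 410.2 ± 13.8 CPM (4.15 ± 0.14, adjusted p = 2.88e-13). Cd274, which encodes the T cell inhibitory ligand PD-L1, rose from 4.22 ± 0.125 to 193.2 ± 9.30 CPM (5.51 ± 0.16, adjusted p = 4.47e-14). At the same time Myc, the growth-promoting transcription factor gene, fell from 1348 ± 102 to 72.6 ± 10.8 CPM (-4.21 ± 0.15, adjusted p = 4.11e-13). Targets of p53, lysosomal genes, genes of cholesterol synthesis and ribosomal protein genes moved up. The calls for lysosomal and ribosomal protein genes were lost with an estimated correlation (adjusted p = 0.183 and 0.459). Mitotic genes did not move together.

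Of 43 interferon-stimulated genes, 42 rose in MB49 cells and 0 fell, with a median of 4.26 (camera adjusted p = 1.97e-15, and adjusted p = 0.00973 with an estimated correlation). The remaining member, Ifih1, named after its values were seen, lay at the floor with 3 counts in the controls and 0 after 8 Gy. Cxcl9, another T cell chemokine gene, had 0 counts in the controls and 155.5 ± 43.5 CPM after 8 Gy, at least 4090-fold higher. Zbp1, a sensor of nucleic acids, likewise went from 0 counts to 40.2 ± 1.74 CPM, at least 1040-fold higher. The interferon-inducible GTPase gene Igtp rose by 10.02 ± 0.20 (adjusted p = 1.43e-15). The serine protease inhibitor gene Serpina3f went from 1 count to 21040 counts, a ratio of 27500 with a 95% counting interval of 4940 to 1090000. Each of the 24 genes of MHC class I presentation rose (median 2.74, camera adjusted p = 1.18e-13, but adjusted p = 0.0847 with an estimated correlation). They included the class I heavy chain gene H2-K1 (2.29 ± 0.14, from 321.2 ± 59.2 to 1572 ± 113 CPM), its light chain gene B2m (2.93 ± 0.17, from 194.5 ± 24.7 to 1485 ± 281 CPM) and the peptide transporter gene Tap1 (5.39 ± 0.16). The immunoproteasome subunit gene Psmb9 (7.71 ± 0.26) and the chaperone gene Calr (1.61 ± 0.12) were others, with adjusted p from 6.17e-14 for Tap1 to 2.33e-09 for Calr. Among 19 measured ligands of T and natural killer cell receptors, 10 rose and 5 fell (median 0.34, camera adjusted p = 0.206). Cd276 and Icosl fell by 1.09 ± 0.14 and 1.08 ± 0.22 on the log2 scale (adjusted p = 3.27e-06 and 0.000362). Of 17 genes of cytosolic DNA sensing through cGAS and STING, 9 rose and 2 fell (median 0.59, camera adjusted p = 0.141). Genes outside the rule and chosen after their values were seen were the nitric oxide synthase gene Nos2 (88.2 ± 12.6 to 2302 ± 504 CPM, 4.71 ± 0.20, adjusted p = 2.96e-12) and the GTPase gene Gbp2 (8.91 ± 0.20, adjusted p = 2.94e-15). So was Ciita, the master regulator of MHC class II genes (5.82 ± 0.27, from 7 counts to 322 counts, adjusted p = 5.44e-11). The interferon genes themselves were barely seen: Ifng had 0 counts in all 4 groups, and Ifnb1 had 0 counts in MB49 controls and 1 after 8 Gy.

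Targets of p53 rose in MB49 cells, 24 of 35 up and 7 down (median 0.92, camera adjusted p = 0.00255, adjusted p = 0.0378 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 496 ± 60.9 to 883.6 ± 78.4 CPM (0.83 ± 0.13, adjusted p = 2.86e-05). The p53 ubiquitin ligase gene Mdm2 rose from 126.8 ± 11 to 351 ± 49.0 CPM (1.47 ± 0.13, adjusted p = 1.74e-08). The stress cytokine gene Gdf15 rose by 2.72 ± 0.21 (adjusted p = 4.57e-09). Trp53 itself fell by 0.92 ± 0.12 on the log2 scale and the target Plk2 fell by 1.34 ± 0.12 (adjusted p = 4.11e-06 and 3.17e-08). Lmnb1, the lamin B1 gene that is often low in senescent cells, fell from 72.7 ± 10.1 to 40.9 ± 2.06 CPM (-0.83 ± 0.12, adjusted p = 6.49e-06). The senescence-associated cell cycle inhibitors Cdkn2a and Cdkn2b stayed near the floor, with 10 and 9 counts over the MB49 controls and 5 and 3 counts after 8 Gy. Of 32 genes of G2 phase and mitosis, 16 rose and 6 fell (median 0.30, camera adjusted p = 0.414). The proliferation marker gene Mki67 stood at 56.2 ± 16.1 CPM in controls and 52.1 ± 12.7 CPM after 8 Gy (-0.11 ± 0.23, adjusted p = 0.681). The topoisomerase gene Top2a rose by 0.96 ± 0.16 and Foxm1, a transcription factor gene of mitotic entry, fell by 1.62 ± 0.16 (adjusted p = 6.52e-05 and 1.09e-07). Kif20a, a mitotic kinesin gene, rose by 0.80 ± 0.11 (adjusted p = 6.36e-06). Genes of DNA replication (15 up and 7 down of 34, median 0.29, camera adjusted p = 0.528) and DNA repair (10 up and 11 down of 33, median -0.07, camera adjusted p = 0.838) went both ways. Of 21 measured replication histone genes 4 rose and 1 fell (median 0.41, camera adjusted p = 0.654). Among 25 BCL2 family and apoptosis genes, 12 rose and 7 fell (median 0.28, camera adjusted p = 0.229).

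Of 19 immediate early genes, 15 fell and 1 rose in MB49 cells, with a median of -1.44, or -1.25 with members near 0 set at their bound (camera adjusted p = 1.11e-05, but adjusted p = 0.286 with an estimated correlation). Fosl1, a component of the AP-1 transcription factor, fell with Myc by 4.06 ± 0.15 on the log2 scale (adjusted p = 4.78e-13). Zfp36, an mRNA decay factor gene named after its values were seen, was the member that rose (0.90, adjusted p = 1.13e-05). Of 41 cytosolic ribosomal protein genes, 40 rose and 0 fell (median 1.27, camera adjusted p = 1.84e-09, but adjusted p = 0.459 with an estimated correlation). Rplp1 rose from 744.6 ± 292 to 2596 ± 379 CPM (1.80 ± 0.22, adjusted p = 2.18e-06). MB49 control replicate 3 stood apart from the other controls toward the irradiated libraries, with 4.41% of its counts in these genes against 3.21 and 3.14%, and without it the median was 1.47. Rpl5, named after its values were seen, was the member that did not pass (0.14, adjusted p = 0.561). Shorter genes moved up in MB49 cells in general, from a median of 0.64 in the octile with a median length of 831 bases to -0.28 in that with 6961 bases. Of 34 lysosomal genes, 30 rose and 0 fell (median 1.12, camera adjusted p = 1.84e-09, but adjusted p = 0.183 with an estimated correlation). These included the lysosomal membrane protein gene Cd68 (2.93 ± 0.13, adjusted p = 3.94e-12), the cholesterol carrier gene Npc2 (2.27 ± 0.13, adjusted p = 1.73e-10) and Glb1, the source of senescence-associated beta-galactosidase activity (0.53 ± 0.13, adjusted p = 0.00151, but 0.23 and adjusted p = 0.10 when libraries were scaled by their totals only). Of 24 genes of cholesterol synthesis, 19 rose and 1 fell (median 0.95, camera adjusted p = 1.11e-05, adjusted p = 0.0378 with an estimated correlation). Insig1 and Mvd rose by 2.28 ± 0.12 and 2.85 ± 0.15 (adjusted p = 4.64e-11 and 5.54e-11). The squalene epoxidase gene Sqle, named after its values were seen, was the member that fell (-0.54, adjusted p = 0.000203).

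The secretory genes of MB49 cells split. Of 39 measured genes of the senescence-associated secretory phenotype (SASP), 15 rose and 15 fell (median -0.10, camera adjusted p = 0.796). The chemokine gene Ccl5 rose by 6.82 ± 0.22, the colony-stimulating factor gene Csf3 by 3.14 ± 0.14 and the interleukin gene Il6 by 2.90 ± 0.39 (adjusted p = 1.17e-13, 6.15e-12 and 7.88e-06). The monocyte chemokine gene Ccl2 fell by 0.99 ± 0.18 on the log2 scale. Larger falls were those of Csf2 (-3.77 ± 0.18), the chemokine gene Ccl20 (-6.37 ± 0.46) and Angptl4 (-5.21 ± 0.19), and adjusted p for the 4 genes ran from 4.82e-13 for Angptl4 to 0.000105 for Ccl2. Il23a, a cytokine subunit gene named as one of the largest falls, fell by 5.45 ± 0.28 (adjusted p = 1.42e-10). Of 24 targets of NF-kB, 10 rose and 11 fell (median -0.15, camera adjusted p = 0.718). The inhibitor gene Nfkbie fell by 2.98 ± 0.13 (adjusted p = 5.29e-12). Of 33 genes of vesicle formation, 16 rose and 7 fell (median 0.31, camera adjusted p = 0.218). The tetraspanin gene Cd81 was up by 2.06 ± 0.12 and the neutral sphingomyelinase gene Smpd3 down (-3.55 ± 0.28), at adjusted p = 1.20e-10 and 6.57e-09. Of 13 heat shock genes, 7 rose and 3 fell (median 0.79, camera adjusted p = 0.141), and the chaperone gene Hspa8 rose by 2.43 ± 0.12 (adjusted p = 1.45e-11). Stress response genes of the unfolded protein and integrated stress responses (8 up and 12 down of 23, median -0.49, camera adjusted p = 0.246) and matrix genes (8 up and 11 down of 25, median -0.04, camera adjusted p = 0.654) had no common direction. The epithelial list had 7 genes up and 2 down of 19, with a median of -0.13 although the camera test leaned upward (adjusted p = 0.798). Urothelial (2 up and 3 down of 8, median -0.73, camera adjusted p = 0.718), pancreatic duct (1 up and 1 down of 9, median -0.17, camera adjusted p = 0.718) and mitochondrially encoded genes (5 up and 0 down of 13, median 0.43, camera adjusted p = 0.654) did not pass either. Of 22 immune cell markers only 5 had enough counts to be tested, and 4 rose (median 1.88, camera adjusted p = 0.206). The pan-leukocyte gene Ptprc had 1 count after 8 Gy and no marker had more than the 4.0 CPM of Ly6g, by library totals without TMM factors. Of 6 measured fibroblast and endothelial markers 3 rose and 0 fell (median 1.09, camera adjusted p = 0.206).

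Across the 14362 genes tested, 5066 were higher and 4540 lower in MB49 cells after 8 Gy, 66.9% of them, and 2972 and 2496 of these by at least 2-fold. Most alternatives also had more genes higher, but not all. Numbers were 4766 higher and 5393 lower with no filter, 4345 and 4639 with the 6 MB49 libraries alone, and 4760 and 5069 without KPC control replicate 1. Adjusted over the list alone, the counts differed for 7 lists. By that adjustment 14 replication genes, 2 histone genes, 5 epithelial genes and 4 mitochondrial genes rose, and 12 NF-kB targets, 13 stress response genes and 16 immediate early genes fell. The number of lists past the test was 7 of 26, a number that other splits of the 6 libraries also reached, though these kept a part of the treatment contrast.

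**Figure D1:**
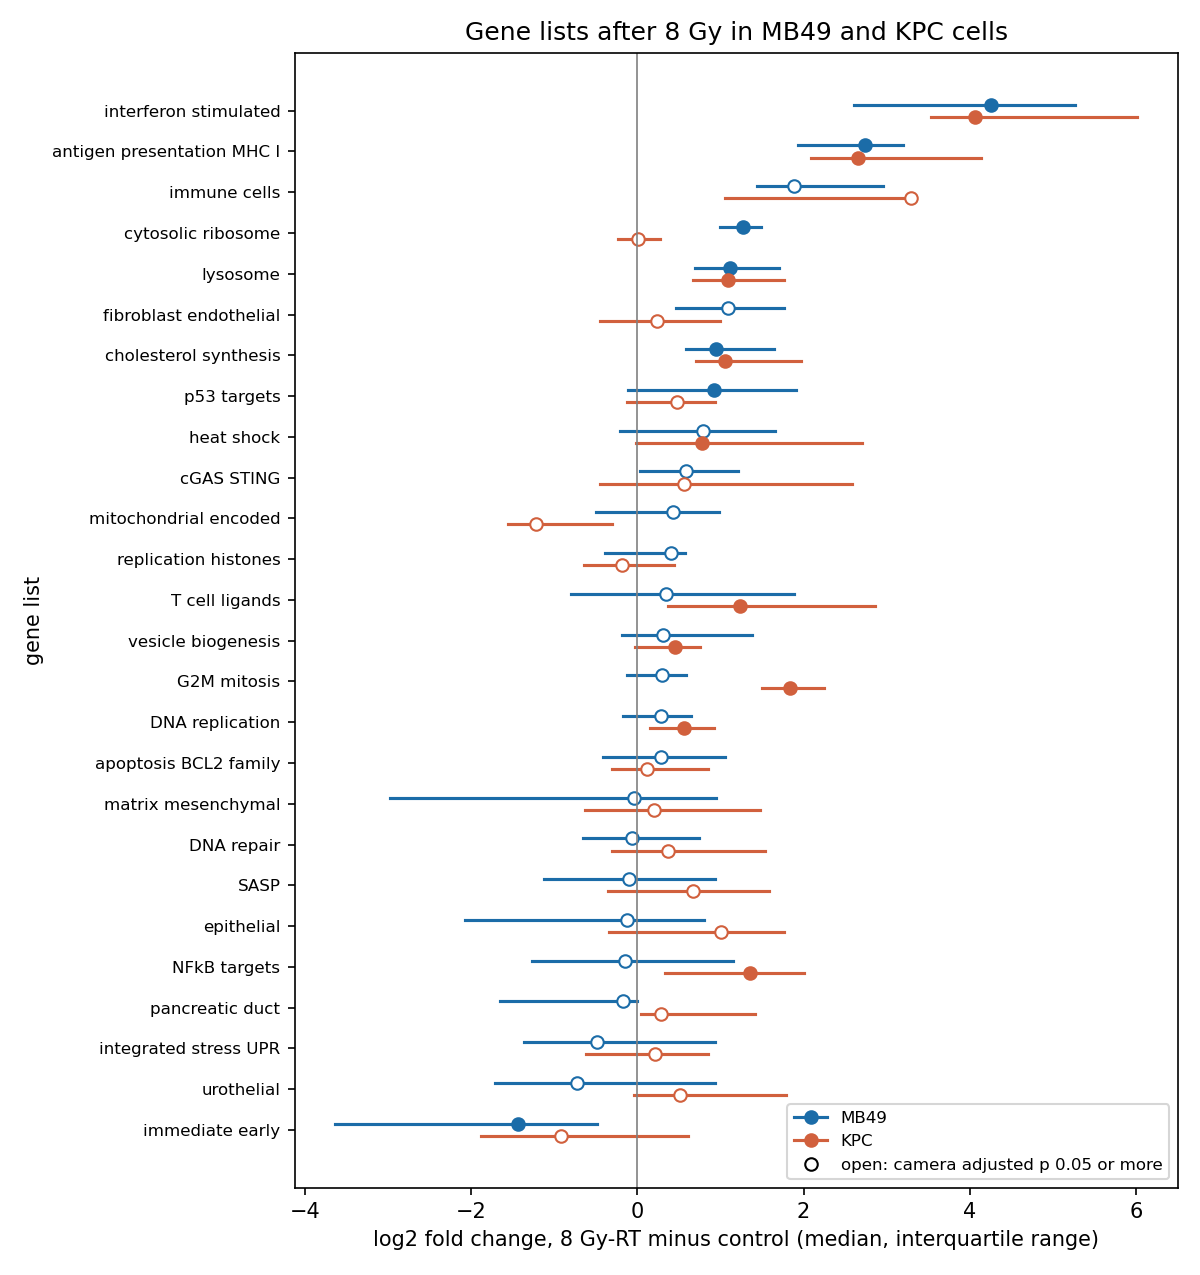
Median log2 fold change (8 Gy minus control, horizontal axis) of each of the 26 gene lists (vertical axis) in MB49 (blue) and KPC cells (orange), with lines for the interquartile range over the tested members of a list and open circles where the camera adjusted p was 0.05 or more. Interferon-stimulated genes lay highest in both lines, at 4.26 and 4.07, while G2/M genes (0.30 and 1.84) and ribosomal protein genes (1.27 and 0.01) lay apart between the lines.

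KPC cells after 8 Gy also carried higher interferon-stimulated and antigen presentation genes, together with higher mitotic, lysosomal and cholesterol synthesis genes and lower Myc. With an estimated correlation the calls for antigen presentation and lysosomal genes were lost (adjusted p = 0.0672 and 0.110). Cxcl10 rose from 20.6 ± 3.71 to 1114 ± 22.6 CPM (5.76 ± 0.15, adjusted p = 7.34e-15) and Cd274 from 3.32 ± 0.890 to 163.8 ± 8.76 CPM (5.62 ± 0.16, adjusted p = 2.12e-14). Ccnb1, the cyclin B1 gene that drives entry into mitosis, rose from 10.7 ± 0.421 to 110.9 ± 8.37 CPM (3.38 ± 0.12, adjusted p = 3.03e-13). Myc fell from 632.1 ± 61.5 to 52.5 ± 3.40 CPM (-3.59 ± 0.15, adjusted p = 1.29e-12). Cdkn1a, by contrast, stood at 930.1 ± 109 CPM in controls and 955.2 ± 70.6 CPM after 8 Gy (0.04 ± 0.13, adjusted p = 0.823), but its change was -0.35 with adjusted p = 0.010 when libraries were scaled by their totals only.

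Each of the 43 interferon-stimulated genes rose in KPC cells (median 4.07, camera adjusted p = 2.61e-27, adjusted p = 0.00181 with an estimated correlation). Cxcl9 rose by 12.52 ± 0.30, from 0.331 ± 0.0746 to 1988 ± 225 CPM (adjusted p = 2.79e-14), and Gbp2 by 9.42 ± 0.20 to 4662 ± 415 CPM (adjusted p = 2.16e-15). Several genes of the largest rises started from 0 or 1 count in the controls. Ciita had 0 counts and 35.1 ± 3.35 CPM after 8 Gy, at least 876-fold higher. The GTPase gene Gbp10 went from 1 to 12112 counts (ratio 15000, 95% counting interval 2690 to 593000). The pore-forming protein gene Mpeg1 went from 1 to 6478 counts (ratio 8030, interval 1440 to 317000), and Ido1, which encodes a tryptophan-degrading enzyme, from 1 to 3512 counts (ratio 4350, interval 781 to 172000). Nos2, chosen after its values were seen, rose from 3.14 ± 0.753 to 7138 ± 632 CPM (11.15 ± 0.27, adjusted p = 2.74e-15). Of the 24 genes of MHC class I presentation, 23 rose (median 2.66, camera adjusted p = 1.24e-13, but adjusted p = 0.0672 with an estimated correlation). The exception was H2-Q6, named after its values were seen, with 0 counts in the KPC controls and 1 after 8 Gy. H2-K1 rose by 2.56 ± 0.14, B2m by 2.32 ± 0.17, from 357.2 ± 72.6 to 1778 ± 55.3 CPM, Psmb9 by 6.26 ± 0.23 and Calr by 1.71 ± 0.12 (adjusted p from 3.02e-13 for Psmb9 to 2.44e-09 for B2m). Of 19 ligands of T and natural killer cell receptors, 13 rose and 2 fell (median 1.23, camera adjusted p = 0.000296, adjusted p = 0.0164 with an estimated correlation). Among them were the adhesion molecule gene Icam1, up (4.02 ± 0.21) and Cd276, down (-0.67 ± 0.14), at adjusted p = 3.64e-11 and 0.000547. Of the 17 genes of cGAS and STING signalling, 9 rose and 5 fell (median 0.56, camera adjusted p = 0.0998). Ifnb1 had 1 count in the KPC controls and 10 after 8 Gy. No marker of immune cells reached 4 CPM in KPC cells by library totals, with 3 of the 5 testable ones up (median 3.29, camera adjusted p = 0.205).

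Of 32 genes of G2 phase and mitosis, 30 rose and 0 fell in KPC cells (median 1.84, camera adjusted p = 5.47e-13, adjusted p = 0.0120 with an estimated correlation). Kif20a rose by 3.26 ± 0.12, the cyclin A2 gene Ccna2 by 3.12 ± 0.14 and Mki67 by 1.62 ± 0.24, from 11.2 ± 0.345 to 34.2 ± 9.72 CPM (adjusted p = 4.00e-13, 6.56e-12 and 3.59e-05). Of 34 genes of DNA replication, 22 rose and 3 fell (median 0.56, camera adjusted p = 0.000976, but adjusted p = 0.128 with an estimated correlation). The cyclin E1 gene Ccne1 rose by 1.89 ± 0.13 and the helicase subunit gene Mcm4 by 1.53 ± 0.12 (adjusted p = 8.04e-10 and 4.93e-09). Genes of DNA repair (16 up and 7 down of 33, median 0.37, camera adjusted p = 0.163) and replication histone genes (1 up and 2 down of 21, median -0.19, camera adjusted p = 0.757) did not pass. Targets of p53 had 19 genes up and 4 down of 35 (median 0.48, camera adjusted p = 0.103). Mdm2 rose from 134.9 ± 8.68 to 207.4 ± 13.8 CPM (0.62 ± 0.12, adjusted p = 0.000293), though this was 0.24 with adjusted p = 0.145 when libraries were scaled by their totals only. Gdf15 and the p53 cofactor gene Trp53inp1 rose by 2.13 ± 0.20 and 1.86 ± 0.16, and the stress gene Sesn2 fell by 1.5 ± 0.13 on the log2 scale (adjusted p = 8.07e-08, 3.06e-08 and 2.27e-08). Trp53 and Lmnb1 fell by 0.50 ± 0.12 and 0.60 ± 0.12 (adjusted p = 0.00152 and 0.000206). Cdkn2a and Cdkn2b had 4 and 2 counts over the KPC controls and 8 and 8 counts after 8 Gy. Of 25 BCL2 family and apoptosis genes, 9 rose and 7 fell (median 0.12, camera adjusted p = 0.372).

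Lysosomal genes rose in KPC cells, 30 of 34 with 1 fall (median 1.09, camera adjusted p = 5.00e-10, but adjusted p = 0.110 with an estimated correlation). Cd68 rose by 6.39 ± 0.16, the alpha-galactosidase gene Gla by 2.83 ± 0.11 and Glb1 by 0.86 ± 0.13 (adjusted p = 3.79e-15, 7.07e-13 and 1.55e-05). The member that fell was Gusb (-0.59, adjusted p = 0.000292), named after its values were seen. Genes of cholesterol synthesis rose, 22 of 24 with 0 falls (median 1.05, camera adjusted p = 1.33e-08, adjusted p = 0.00980 with an estimated correlation). They were led by Nsdhl (3.23 ± 0.13) and Insig1 (3.01 ± 0.13), at adjusted p = 1.17e-12 and 2.23e-12. Of 24 targets of NF-kB, 18 rose and 4 fell (median 1.35, camera adjusted p = 0.00112, but adjusted p = 0.110 with an estimated correlation). The acute phase gene Saa3 rose by 4.33 ± 0.22, whereas the signalling adaptor gene Traf1 and the inhibitor gene Nfkbie fell by 5.66 ± 0.18 and 2.09 ± 0.13 on the log2 scale (adjusted p = 3.56e-11, 6.61e-14 and 4.48e-10). Among 39 SASP genes, 17 rose and 10 fell (median 0.67, camera adjusted p = 0.177). Ccl2 rose by 4.68 ± 0.43 from 8 counts to 174 counts (6.02 without KPC control replicate 1). Ccl5 rose by 3.59 ± 0.16, and the growth factor binding protein gene Igfbp4 fell by 4.08 ± 0.16 (adjusted p = 6.04e-08 for Ccl2, 3.19e-12 and 6.84e-13). Il6 had 0 counts in the controls and 55 after 8 Gy, at least 22.7-fold higher. Of 13 heat shock genes, 8 rose and 1 fell (median 0.78, camera adjusted p = 0.0118, but adjusted p = 0.0695 with an estimated correlation). They included Hspa8 (4.37 ± 0.13) and the heme oxygenase gene Hmox1 (2.81 ± 0.13), at adjusted p = 2.51e-14 and 1.00e-11. Of 33 genes of vesicle formation, 20 rose and 6 fell (median 0.45, camera adjusted p = 0.0325, but adjusted p = 0.128 with an estimated correlation). Hgs, a sorting component of endosomes, and Steap3 rose by 1.74 ± 0.14 and 1.77 ± 0.14, and Ist1, a regulator of membrane scission, fell by 1.33 ± 0.11 (adjusted p = 1.11e-08, 6.65e-09 and 7.72e-09). This list's call ended without KPC 8 Gy replicate 2 (adjusted p = 0.0554) and with scaling by totals only (median 0.07, adjusted p = 0.121).

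The remaining lists of KPC cells did not pass the test. Immediate early genes had 6 up and 12 down of 19 (median -0.92, camera adjusted p = 0.117), with Fosl1 down (-3.31 ± 0.14, adjusted p = 2.55e-12) beside Myc. Ribosomal protein genes had 8 up and 5 down of 41 (median 0.01, camera adjusted p = 0.80, and a median of -0.10 with upper quartile scaling and -0.37 with scaling by totals only). Mitochondrially encoded genes had 2 up and 4 down of 13 (median -1.22, camera adjusted p = 0.163). Stress response genes (8 up and 7 down of 23, median 0.21, camera adjusted p = 0.825), matrix genes (11 up and 7 down of 25, median 0.20, camera adjusted p = 0.205) and epithelial genes (10 up and 2 down of 19, median 1.01, camera adjusted p = 0.0879) did not pass. Urothelial genes (4 up and 1 down of 8, median 0.51, camera adjusted p = 0.257), pancreatic duct genes (3 up and 2 down of 9, median 0.28, camera adjusted p = 0.641) and fibroblast and endothelial markers (1 up and 2 down of 6, median 0.24 although the camera test leaned downward, adjusted p = 0.852) went both ways. Among the largest falls over all genes were the adhesion protein gene Cdsn, from 540.7 ± 8.71 to 4.17 ± 0.420 CPM (-7.02 ± 0.16, adjusted p = 2.16e-15), and the carbonic anhydrase gene Car6 (-5.66 ± 0.16, adjusted p = 1.25e-14). Across all genes 4490 were higher and 4596 lower in KPC cells after 8 Gy, 63.3% of those tested, and 2509 and 2514 of these by at least 2-fold. The balance depended on the processing: 4737 higher and 4337 lower with DESeq2 size factors, and 4821 and 4270 with its own test. It was 4019 and 5080 with upper quartile factors, 4794 and 4762 with no filter, and 4457 and 4290 without KPC control replicate 1. Adjusted over the list alone, the counts differed for 8 lists. There 31 mitotic genes, 14 T cell ligands, 31 lysosomal genes, 23 cholesterol synthesis genes and 7 immediate early genes rose, and 1 histone gene fell. Of others, 4 ribosomal protein genes rose and 2 fell, and 10 apoptosis genes rose and 8 fell. The number of lists past the test was 10 of 26, and other splits of the 6 libraries, which kept a part of the treatment contrast, reached it as well. With scaling by totals only, the median of all genes in KPC moved from -0.01 to -0.39 and the share of higher genes among those called from 49.4% to 31.8%. In MB49 the shifts were from 0.04 to -0.23 and from 52.7% to 39.5%.

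**Figure D2:**
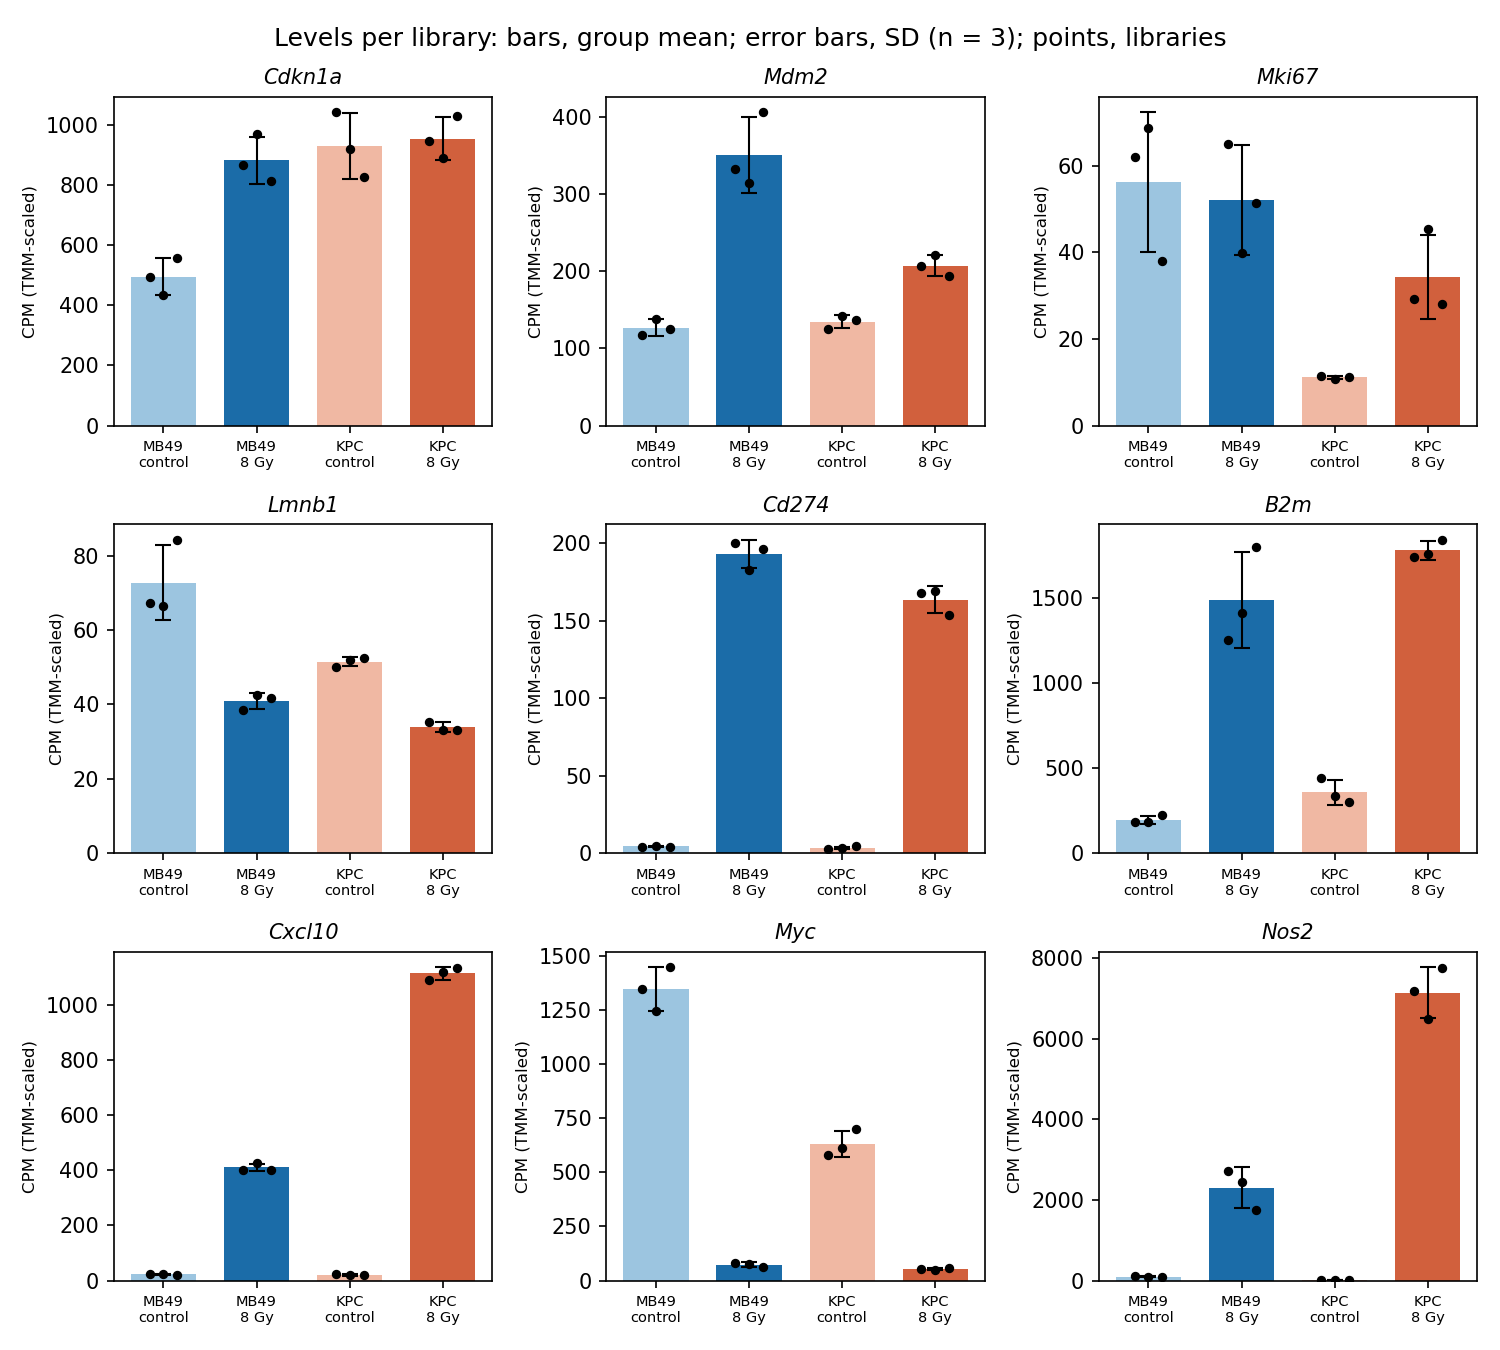
Levels of 9 genes in TMM-scaled CPM (vertical axes, each from 0) in the 4 groups, with bars for the mean, error bars for the SD (n = 3) and points for the libraries. Cd274, B2m, Cxcl10 and Nos2 were higher and Myc and Lmnb1 lower in every irradiated library than in the controls of its line, while Cdkn1a rose in MB49 (496 to 883.6 CPM) and stood at 930.1 and 955.2 CPM in KPC.

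The difference between the lines' responses was tested as the KPC change minus the MB49 change. Mitotic genes responded apart: 30 of 32 were more positive in KPC and 0 less (median difference 1.56, camera adjusted p = 1.88e-16, adjusted p = 0.0154 with an estimated correlation). Among them were Foxm1 (3.19 ± 0.23), Ccnb1 (3.08 ± 0.16) and Mki67 (1.73 ± 0.33), at adjusted p = 1.58e-08, 4.50e-10 and 0.000803. Targets of p53 responded more in MB49, 20 of 35 with a lower and 4 with a higher KPC change (median -0.68, camera adjusted p = 0.00146, adjusted p = 0.0387 with an estimated correlation). The difference was -0.85 ± 0.17 for Mdm2 and -3.80 ± 0.25 for the carbonyl reductase gene Dcxr (adjusted p = 0.000903 and 7.20e-09). For Cdkn1a it was -0.79 ± 0.19 (adjusted p = 0.00249), but -0.12 with adjusted p = 0.524 once a trend with gene length was removed. Plk2, which fell in MB49, differed the other way (1.20 ± 0.17, adjusted p = 2.56e-05). The shared interferon response, in contrast, gave no call for a difference as a group. There 15 genes were more positive and 10 less positive in KPC of 43 (median 0.51, camera adjusted p = 0.367). The numbers were 7 and 8 of 24 for MHC class I presentation (median 0.18, camera adjusted p = 0.661). The test was passed by 9 of 26 lists, and other splits within the lines, which kept a part of the treatment contrasts, reached that number too.

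Targets of NF-kB had a more positive change in KPC by camera with the preset correlation but not with the estimated one. By fry this difference was called (adjusted p = 2.36e-05). Of 24 genes, 15 had a more positive and 2 a less positive change there (median difference 1.15, camera adjusted p = 0.000105, but adjusted p = 0.124 with an estimated correlation). The difference was 4.87 ± 0.26 for Icam1 and 5.67 ± 0.47 for Ccl2 (7.10 without KPC control replicate 1), which both fell in MB49 and rose in KPC. It was 5.88 ± 0.54 for Csf2, which fell in MB49 and had 4 counts in KPC controls and 15 after 8 Gy, and the 3 genes had adjusted p of 6.68e-10, 9.31e-08 and 3.11e-07. SASP genes were not called for a difference (17 more positive and 7 less of 39, median 0.68, camera adjusted p = 0.0682). Nos2, chosen after its values were seen, differed by 6.45 ± 0.28 (adjusted p = 4.90e-11). Its level was lower in KPC than in MB49 controls and higher in KPC after 8 Gy, so a part of the difference lies in the controls. Other induced genes rose more in MB49, with differences of -3.23 ± 0.27 for Ccl5, -3.10 ± 0.25 for Igtp and -1.45 ± 0.37 for Psmb9 (adjusted p = 1.09e-07, 7.84e-08 and 0.00465), whose MB49 controls lay lower. Igfbp4, which rose in MB49 (1.11 ± 0.14) and fell in KPC, had a difference of -5.19 ± 0.21 (adjusted p = 2.76e-11). T cell ligands (6 more positive and 1 less of 19, median 0.42, camera adjusted p = 0.0209, but adjusted p = 0.124 with an estimated correlation) and DNA replication genes (17 and 5 of 34, median 0.50, camera adjusted p = 0.00708, but adjusted p = 0.381 with an estimated correlation) were shifted toward KPC. So were immediate early genes (13 and 1 of 19, median 1.09, camera adjusted p = 5.09e-05, but adjusted p = 0.381 with an estimated correlation). Ribosomal protein genes were shifted toward MB49, 37 of 41 with a lower KPC change and 0 with a higher (median -1.20, camera adjusted p = 3.28e-11, but adjusted p = 0.492 with an estimated correlation). Rplp1 stood at -1.90 ± 0.31 (adjusted p = 0.000132). DNA repair genes (12 and 4 of 33, median 0.46, camera adjusted p = 0.0444, adjusted p = 0.566 with an estimated correlation) and mitochondrially encoded genes (0 and 5 of 13, median -1.23, camera adjusted p = 0.0215, adjusted p = 0.588 with an estimated correlation) passed narrowly. The call for DNA repair ended when any of 6 libraries was left out (adjusted p = 0.0559 to 0.0780) and that for mitochondrial genes without MB49 8 Gy replicate 3 (adjusted p = 0.0546). With a trend with gene length removed, both calls ended (medians 0.39 and -0.36, adjusted p = 0.175 and 0.259).

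Gene by gene, the response differed between the lines for 6162 of the 14362 genes, 3002 more positive and 3160 more negative in KPC. Which direction had more genes depended on the processing: 2632 and 3520 with totals only, 2587 and 3656 with upper quartile factors, 3240 and 2934 with DESeq2 size factors, 3343 and 2930 with its own test, 3363 and 2977 with a length trend removed, 3677 and 2806 with no filter, and 3365 and 2517 without KPC control replicate 1. Adjusted over the list alone, 31 mitotic and 19 replication genes were more positive in KPC, and 39 ribosomal protein and 3 mitochondrial genes less positive. The direction was nonetheless often shared: 2905 genes rose in both lines, where independent lists of these sizes would give 1584, and 2861 fell in both, where 1453 would be given. Opposite calls were made for 891 genes against 3041 from independent lists, and the log2 fold changes correlated with r = 0.565 across genes, which are not independent replicates. With at least 2-fold changes in both lines, 1366 genes rose in both, 1355 fell in both and 168 went opposite ways. The lines share no control libraries, so this overlap does not come from a common baseline.

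**Figure D3:**
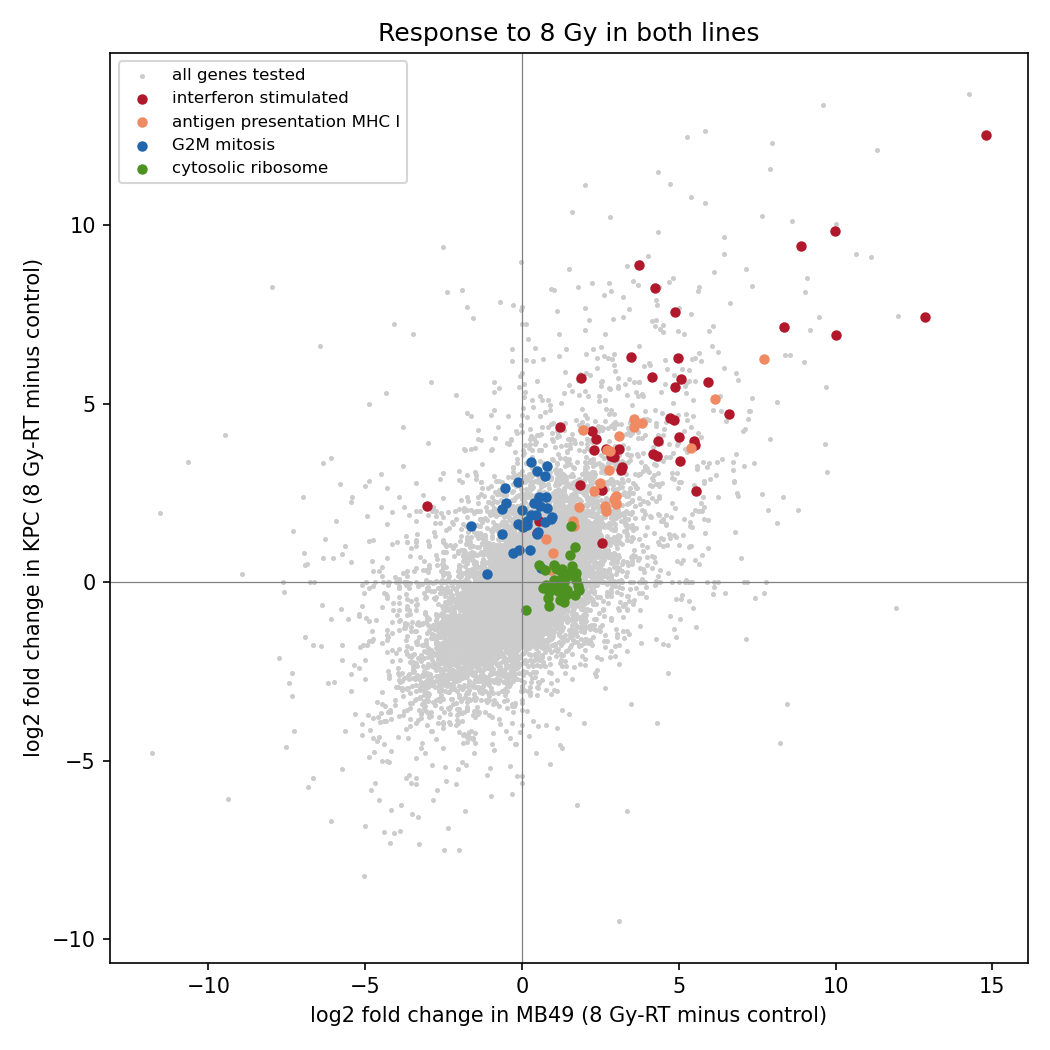
Fitted log2 fold change after 8 Gy in MB49 (horizontal axis) and KPC cells (vertical axis), a point for each of the 14362 genes tested, with 4 gene lists in colour and fitted values, not bounds, for genes at 0 in a control group. Interferon-stimulated and MHC class I genes lay to the upper right (medians 4.26 and 2.74 in MB49, 4.07 and 2.66 in KPC), whereas ribosomal protein genes were spread along the horizontal axis and mitotic genes lay along the vertical axis.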

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

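The tests of explanations for the first 3 patterns were chosen after the results were seen; the counts over other splits of the libraries were planned.

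Interferon-stimulated and MHC class I genes rose in both lines, although Ifng had 0 counts and Ifnb1 at most 10 counts in any group; with an estimated correlation the MHC class I list was not called (adjusted p = 0.0847 in MB49 and 0.0672 in KPC). Scaling between libraries does not account for it, since the lowest median of the 2 lists in either line under 3 other scalings was 2.28. Immune cells carried into the cultures are argued against by their own genes: by library totals without TMM factors, B2m rose by 1160 and 1120 CPM, while the highest marker of the immune cell list in an irradiated group was Ly6g at 4 CPM, with Ptprc at 0.0152 CPM and Tyrobp at 0 in irradiated MB49 cells. A response of the interferon gamma type rather than type I was looked at with 11 genes named for gamma. Their medians were 4.71 in MB49 and 6.21 in KPC (the value of H2-Eb1, with 1 count in the controls replaced by a floor of 3 and library totals unscaled, where the fit gave 7.69), against 4.30 and 4.36 for 11 type I genes. The gamma genes include Nos2, Gbp2 and Ciita, which were chosen in MB49 after their values were seen, and the MB49 median is the value of Nos2. Genes picked in these data cannot decide for gamma in MB49. There the difference was the smaller of the 2, at 0.41, and the question stays open. In irradiated MB49 cells the type I genes reached 0.549 to 28.4 CPM by library totals, from 0.0489 to 4.27 CPM in controls. The gamma genes there stood at 0.968 to 2350 CPM, from 0 to 174 CPM. In irradiated KPC cells the type I genes reached 23.6 to 1210 CPM, from 0.0571 to 60.5 CPM in controls. The gamma genes of KPC stood at 0.924 to 6060 CPM, from 0 to 153 CPM. Cd74, a gamma gene named after its values were seen, fell in MB49 (-0.62) and rose in KPC (2.54). Also open are the source of any interferon, whether made by the cells after radiation or added to the culture, and whether cells had been made senescent first.

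Genes of G2 phase and mitosis rose in KPC after 8 Gy, and the change differed from that in MB49. Scaling and single libraries do not account for it, as the lowest median was 1.46 under 3 other scalings and 1.74 without any 1 of the 6 KPC libraries. The untreated KPC cells stand out instead: their median log2 CPM over the list was 3.90, against 5.56 and 5.88 in the MB49 control and 8 Gy groups and 6.60 in irradiated KPC cells, which puts them 1.66 below the lower MB49 group (difference -1.66). Few cycling cells in the KPC control cultures, for instance at high density, could give this low level, so the rise may reflect the controls as much as the radiation. Other values of KPC do not all go with it. Genes of DNA replication rose less (median 0.56), replication histone genes had a median of -0.19, and Myc stood higher in the controls than after 8 Gy. A level set against another line cannot decide this. Culture density was not recorded in the labels, and a plain difference between the lines or cells held in G2 stays open and untested.

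Ribosomal protein genes rose in MB49 and not as a group in KPC, though with an estimated correlation neither the rise nor the difference was called (adjusted p = 0.459 and 0.492). These genes are short, and short genes rose in MB49 in general, so each was set against the 100 other genes nearest in length, whose median was 0.57. A median of 0.67 remained (interquartile range 0.37 to 0.97, 40 of 41 genes above 0), against 0.05 in KPC, so a trend with length alone does not account for all of it, though it may account for part. Scaling leaves a lowest median of 0.98. RNA integrity was not given per library, and a difference in it or a real rise of these mRNAs cannot be decided from these values.

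Counts over other splits were set beside the real ones. Genes that differed in response numbered 6162, reached by 1 of 100 splits (the real one, highest other 4069). That share argues against chance in how the libraries were grouped as the source of this count. Genes changed the same way in both lines numbered 5766, also reached by 1 of 100 (highest other 0), from which no conclusion is drawn. The splits that kept the real grouping in 1 line only gave 736 to 4069 genes for the difference, so the splits bear on an effect of the treatment and not on whether the responses of the lines were equal. A line with changed grouping called at most 1 gene, so the shared count says no more than the counts of the single lines. The splits of 6 libraries number 10, too few for a share under 0.05. They gave the real count of genes 1 time in 10 for MB49 (9606, highest other 0), KPC (9086, highest other 1) and the controls (9672, highest other 0). Counts of lists were less separate: 8 of 10 splits reached the 7 lists of MB49 (highest other 11), 4 of 10 the 10 lists of KPC (highest other 12), and 41 of 100 the 9 lists of the difference (highest other 14). Every other split of a line still held unequal shares of control and irradiated libraries in its arms, so it kept a part of the treatment contrast. Such splits of a line called lists although they called at most 1 gene. The counts of lists therefore neither exclude chance nor speak for it, and the number of lists says little about the treatment.

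Other results were singled out because the test of the difference between the lines passed, here as KPC change minus MB49 change on the log2 scale. Among gene lists the median differences were -0.68 for p53 targets, 1.56 for mitosis, 0.50 for DNA replication, 0.46 for DNA repair and 0.42 for T cell ligands. They were 1.15 for NF-kB targets, -1.23 for mitochondrially encoded genes, -1.20 for ribosomal proteins and 1.09 for immediate early genes. With an estimated correlation only the lists of p53 targets and mitosis were called, and the other 7 had adjusted p of 0.124 to 0.588. Among cytokine and adhesion genes, Ccl2 differed by 5.67 (7.10 without KPC control replicate 1), Icam1 by 4.87, Csf2 by 5.88 and Ccl5 by -3.23. Nos2 differed by 6.45, Igtp by -3.10 and Psmb9 by -1.45. Among cell cycle and p53 genes the differences were -0.79 for Cdkn1a (-0.12, adjusted p = 0.524, once a trend with gene length was removed), -0.85 for Mdm2, -3.80 for Dcxr, 1.20 for Plk2, 1.73 for Mki67, 3.08 for Ccnb1 and 3.19 for Foxm1. Igfbp4 differed by -5.19 and Rplp1 by -1.90.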

How the results depend on the processing

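All alternatives were planned except 3 added after the data were seen: leaving out the 18S row, scaling by library totals only, and an offset removing a trend with gene length. The test against a log2 fold change of 1 asks a stricter question and left 3632 genes in MB49, 3232 in KPC, 1436 for the difference of responses and 3949 between the controls. The estimated correlation left 3, 4 and 2 gene lists, as it widens the test of any list whose genes vary together. Every other count stayed within 1.5 times its main value. Without any 1 library, genes numbered 8932 to 9829 in MB49, 8297 to 9524 in KPC, 5451 to 6547 for the difference, 8988 to 10030 between the controls and 5343 to 5843 for changes shared by the lines, and lists 7 to 7 in MB49, 9 to 11 in KPC and 8 to 9 for the difference. DESeq2 called 9497, 9091, 6273 and 9805 genes for the 4 comparisons and limma-voom 9689, 9144, 6435 and 9829. Without the 18S row KPC had 9080 genes, and without KPC control replicate 1, which carried most of it, 8747. Replicate numbers did not pair the libraries: deviations of the 18 same-numbered pairs correlated at -0.197 to 0.135 (median -0.0235), 2 of them above 0.1, and 0 libraries went best with their own number in all groups. With the replicate block the counts were 9190, 8723, 5635 and 9325 genes, 5459 shared genes and 7, 10 and 9 lists. The block changed no list's side of the threshold. Over 3606 combinations of a named gene and an alternative, 3567 kept their side of the threshold, 25 lost it, 14 gained it and 0 called genes reversed; most losses came from the test against a log2 fold change of 1. Over 1554 combinations of a list and an alternative, 1508 kept their side, 31 lost it, 15 gained it and 0 reversed. The call for DNA repair in the difference was lost with the stricter filter (adjusted p = 0.0538), with totals only (0.0504), with the length trend removed (0.175) and without any of 6 single libraries (0.0559 to 0.0780). That for mitochondrial genes was lost without MB49 8 Gy replicate 3 (adjusted p = 0.0546) and with the length trend removed (median -0.36, adjusted p = 0.259), and that for T cell ligands with no filter (adjusted p = 0.0671). The stress response list was called in the difference without MB49 control replicate 2, MB49 8 Gy replicate 2 or KPC control replicate 1 (adjusted p = 0.0431, 0.0367 and 0.0317). It was also called with no filter (0.00459) and with the length trend removed (0.0221), as were SASP genes (0.00810 and 0.00947). With no filter cholesterol synthesis (0.0176) and matrix genes (0.0160) were called in the difference too. In KPC the epithelial list was called without MB49 control replicate 3 (adjusted p = 0.0486), with no filter (0.0331) and with totals only (0.0201). With no filter the cGAS and STING, immediate early and mitochondrial lists were called in KPC as well (adjusted p = 0.0331, 0.0190 and 0.0331). The vesicle list of KPC was lost without KPC 8 Gy replicate 2 (0.0554) and with totals only (0.121). Scaling matters for small changes: totals only moved the median of all genes by enough that Cdkn1a in KPC read -0.35 (adjusted p = 0.010), and upper quartile factors moved the KPC median from -0.01 to -0.12 and that of the difference from -0.02 to -0.13. The cause of these changes was not tested. Depth limits the genes near 0: Ifng, Ifnb1, Cdkn2a and Cdkn2b had at most 10 counts over any group and were left untested by the filter.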

Other observations

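The pathway, transcript class and ferritin comparisons in this part were chosen after the data were seen.

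Genes of ribosome assembly in the nucleolus fell in both lines, opposite to the ribosomal protein genes of MB49. Of 70 genes in the deposited annotation of ribosome biogenesis, 54 fell and 1 rose in MB49 (median -0.76, camera adjusted p = 1.04e-08, but adjusted p = 0.325 with an estimated correlation). In KPC 46 fell and 3 rose (median -0.81, camera adjusted p = 4.74e-07, but adjusted p = 0.167 with an estimated correlation). The nucleolar protein genes Nop56, Nop58 and Gnl3 fell by 3.88 ± 0.12, 3.38 ± 0.20 and 3.17 ± 0.18 on the log2 scale in MB49 (adjusted p = 6.17e-14, 1.24e-10 and 8.58e-11). In KPC they fell by 2.81 ± 0.11, 2.66 ± 0.19 and 2.61 ± 0.18 (adjusted p = 9.26e-13, 2.82e-09 and 1.0e-09). Myc, a known activator of this gene group, fell in both lines as well.

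Genes of glutathione metabolism rose in both lines, 38 of 49 with 3 falls in MB49 (median 1.16, camera adjusted p = 1.18e-06, but adjusted p = 0.325 with an estimated correlation). In KPC 30 rose and 7 fell (median 1.15, camera adjusted p = 0.000376, but adjusted p = 0.378 with an estimated correlation). Gclm, a subunit of the first enzyme of glutathione synthesis, rose by 2.99 ± 0.12 in MB49 and 3.18 ± 0.11 in KPC (adjusted p = 1.06e-12 and 3.03e-13). The glutathione transferase genes Mgst1 (3.14 ± 0.17 and 4.05 ± 0.18) and Gsta4 (3.83 ± 0.16 and 2.02 ± 0.15) rose in both as well, at adjusted p = 6.01e-11 and 5.11e-12 for Mgst1 and 1.74e-12 and 2.66e-09 for Gsta4. The iron storage genes Fth1 and Ftl1 became some of the most abundant transcripts. Fth1 rose from 2999 ± 333 to 19980 ± 1250 CPM in MB49 (2.74 ± 0.15, adjusted p = 4.82e-11) and by 1.95 ± 0.14 in KPC (adjusted p = 2.71e-09). Ftl1 rose by 2.61 ± 0.16 and 1.98 ± 0.16 (adjusted p = 2.37e-10 and 6.82e-09). The heme oxygenase gene Hmox1, which frees iron from heme, rose by 1.66 ± 0.13 in MB49 and 2.81 ± 0.13 in KPC (adjusted p = 5.04e-09 and 1.0e-11).

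Genes of oxidative phosphorylation rose in MB49, 91 of 117 with 5 falls (median 0.89, camera adjusted p = 2.75e-07, but adjusted p = 0.679 with an estimated correlation). The change was lower in KPC for 78 and higher for 5 (median difference -1.15, camera adjusted p = 6.88e-11, but adjusted p = 0.850 with an estimated correlation). Short genes rose in MB49 in general: the octile of genes with a median length of 831 bases had a median of 0.64 there and -0.06 in KPC. This pathway was not set against genes of like length, so the trend with length cannot be told apart from a change of the pathway. MB49 control replicate 3 stood apart toward the irradiated libraries, with Uqcrh at 43.8 CPM against 22 and 20.3 in the other controls (125.7 to 201.3 after 8 Gy). The short genes Ndufb3, Atp5me and Uqcrh rose by 1.93 ± 0.20, 2.53 ± 0.30 and 2.52 ± 0.28 in MB49 (adjusted p = 2.48e-07, 6.08e-06 and 5.33e-06). In KPC they stood at 0.38 ± 0.20, 0.53 ± 0.29 and 0.33 ± 0.27 (adjusted p = 0.104, 0.127 and 0.301), though all 3 passed with a fit of the 6 KPC libraries alone (adjusted p = 0.0130, 0.00793 and 0.0499). Over the 332 pathways of 10 to 300 genes, 71 were called in MB49, 97 in KPC and 28 for the difference, and 0 with an estimated correlation in each.

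Classes of transcripts were counted, and no test between them was run. In KPC cells, of 344 antisense genes 148 fell and 34 rose (median -0.89), and of 213 processed transcripts 96 fell and 27 rose (median -0.92). Of 360 long intergenic noncoding genes 131 fell and 65 rose (median -0.54), while 12539 protein-coding genes had a median of 0. In MB49 the same classes had medians of -0.06, -0.30 and -0.07, with 0.05 for protein-coding genes. The strand used in counting is not given, and no cause was tested. Genes with 1 annotated exon had a median of -0.32 in KPC (278 down and 143 up of 864) and -0.08 in MB49.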
